A study of Mus musculus with 8 samples.

How the data were processed

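Gene expression was measured by bulk RNA sequencing of adult mouse testis, in 4 libraries labelled Ssty2 knockout and 4 labelled wild type. Per the labels' protocols, total RNA was isolated with TRIzol, treated with DNase and made into libraries with a TruSeq RNA kit; the protocols do not say whether the kit kept the strand of the transcripts. The authors deposited a table of raw counts per Ensembl gene, whole numbers with no normalization, in 1 column per library. Per the submitters' processing notes, FastQC, Trimmomatic, STAR, featureCounts and DESeq2 were used with the mouse build mm39. Their versions, their settings, the annotation release, the treatment of reads that map to several places and the strand setting of the counting are not given in the sources used here. Near-identical gene copies could therefore have had their reads split or dropped, and reads of overlapping or antisense genes cannot be told apart.

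The table held 56748 genes, of which 14839 had no count in any library. Totals ran from 18036708 to 24415587 counts per library, so that 3 counts, the limit that a count of 0 allows, were worth between 0.117 and 0.175 CPM (counts scaled to the library total) in a single library and 0.0383 CPM over the 4 knockout libraries. Intervals and such limits cover counting error only. The labels do not state that the replicates are separate animals, so the p-values measure only the spread between these libraries, which may be technical. Pearson's r of log2 CPM lay between 0.9852 and 0.9918 for pairs of libraries within a group and between 0.9586 and 0.9667 for pairs across groups. Chi-square values of the counts per degree of freedom ran from 4.517 to 9.398 within groups, so no pair agreed within sampling noise and all 8 libraries were counted separately.

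Gene names, gene types, chromosome membership and the order of neighbouring genes were taken from the GENCODE vM21 annotation of GRCm38, supplemented by RefSeq symbols. That build differs from the one the submitters name, so it was used for names, chromosomes and order only and no coordinates are given. A symbol was found for 52073 genes, which held between 98.93% and 99.59% of each library's counts. Every pair of transcripts was also compared for shared 31-base words, and the percentage of a gene's words found in any other gene was taken as a measure of how far its reads could be shared; genes with under 1% are called genes with little sharing.

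Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test on the counts with genotype as the only term. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 21952, and libraries were scaled by the trimmed mean of M-values (TMM). P-values were adjusted by the Benjamini-Hochberg method over all tested genes and called under 0.05. A fold change is the knockout over the wild type, and CPM values are scaled by TMM and given as mean ± SD with n = 4 per group. Gene lists and chromosomes with at least 3 tested genes were tested with camera from limma 3.58.1, which compares a list with all other genes, at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance in 1 direction. Values of single measures per library were compared by a two-sided exact permutation test, whose smallest p with 4 against 4 is 0.0286. Shares of genes were compared by Fisher's exact test, in which genes are treated as independent, which they are not.

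The tests, the rule for naming genes and 28 gene lists were fixed before the data were examined. The lists hold markers of spermatogonia, meiotic spermatocytes, round spermatids, elongating spermatids with chromatin compaction, sperm flagellum and motility, sperm-egg interaction and acrosome, Sertoli cells, Leydig cells, peritubular myoid cells, endothelial cells, macrophages and immune cells, erythroid cells and epididymis. Further lists hold multicopy genes of the Y long arm, single-copy genes of the Y short arm, multicopy and single-copy X-linked spermatid genes, autosomal multicopy spermatid genes, the piRNA pathway, regulators of meiotic sex chromosome silencing and spermatid chromatin, immediate early and stress genes, apoptosis and p53 response, interferon response, innate sensing receptors on the X, cholesterol synthesis, mitochondrially encoded genes, cytosolic ribosomal proteins and replication-dependent histones. Several lists share members. The genes named are Ssty2 and every other gene whose symbol starts with Ssty, the 12 called genes with the largest rise and the 12 with the largest fall, up to 4 members of each list with the smallest p, and up to 5 genes each of the X and the Y with the smallest p. For the largest changes, a mean log2 CPM of at least 1, no overlap between groups and a symbol that is not a model, clone or pseudogene name were required. Members of a list named beyond this rule, because 5 or fewer of the list went that way, were chosen after their values were seen, as were other genes said to have been. Not every such member is reported here.

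Along the Y, genes with at least 20 counts over all libraries were set in annotation order, and those whose pooled knockout CPM was under 5% of wild type were called near zero; both limits were set after the data were seen. Their order was compared with 100000 shuffled orders. A gene with 0 counts in the knockout group has a fold given as a lower bound against 3 counts over the group.

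The alternatives were DESeq2 1.42.0, limma-voom, median-ratio (RLE) factors, library totals without factors, no count filter, a stricter filter of 1 CPM in at least 4 libraries, the replicate number as a block, each library left out in turn, multicopy and unplaced genes left out, an adjusted p under 0.01 and a change of at least 2-fold. TMM factors from autosomal genes, and list and chromosome tests under library totals and under both filters, were added after the data were seen. Under library totals alone, the median log2 fold change of all tested genes moved to -0.15, from -0.01 with TMM, since the TMM factors were 1.05 ± 0.0124 in wild type and 0.952 ± 0.00741 in knockout.

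The edgeR test was also run on simulated counts drawn from these libraries' means, with 49 genes changed at each of 4 sizes among 21617 genes tested for this comparison. It called 91.8% of genes raised by 1 on the log2 scale, 42.9% of those raised by 0.5, 81.6% of those changed by -1 and 57.1% of those changed by -0.5. Of 21421 genes left unchanged, 0.0607% were called, which made up 8.84% of all calls. The simulated changes were few and even in both directions, whereas the real comparison called 53.5% of tested genes. The simulation therefore does not test the scaling or the error rate where so many genes change. A simulated list of 100 unchanged genes had an adjusted p of 0.812.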

Results

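Transcript levels were measured by RNA sequencing in adult mouse testis lacking Ssty2 (4 libraries) and in wild-type testis (4 libraries). Ssty2 is a gene of the mouse Y chromosome that is present in many copies on the long arm and is expressed in spermatids, the haploid cells that mature into sperm. The comparison asks which genes differ between testis in which the Ssty2 repeats were deleted and wild-type testis. The submitters' title links the deletion to the sex ratio of the mice. Depth ran from 18763650 to 24415587 counts in wild type and from 18036708 to 22639737 in knockout (n = 4 each; exact permutation p = 0.743). The 10 largest genes took 3.25% ± 0.272 of the counts in wild type and 3.47% ± 0.116 in knockout (mean ± SD, exact permutation p = 0.171).

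Ssty2 (ENSMUSG00000095302) had no count in any of the 4 knockout libraries and 56, 78, 83 and 45 counts in the wild-type libraries. Its level in wild type was 2.92 ± 0.552 CPM, and it was at least 77.0-fold lower in knockout, against a limit of 3 counts over the group (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.80e-08). The related gene Ssty1 had no count in any of the 8 libraries, wild type included; how reads that map to several places were counted is not given, so this does not show that it was not expressed. Sly, another multicopy gene of the Y long arm that is transcribed in spermatids, had 1 count in the knockout group against 796 in wild type (8.84 ± 1.79 CPM in wild type). That is 0.143% of the wild-type level, with a 95% counting interval from 0.0036% to 0.796%. Gm20736 fell from 8.30 ± 1.64 to 0.151 ± 0.0686 CPM (adjusted p = 1.79e-10), and Gm20738 had no count in knockout and 0.791 ± 0.233 CPM in wild type. All 4 tested members of the Y long-arm multicopy list fell, also when adjusted over the list alone (camera adjusted p = 5.64e-12, and adjusted p = 0.0102 with an estimated correlation). Srsy, a further member, had no count in any library, to which the same limit applies.

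The loss of counts was not limited to Ssty2. Of 191 Y-linked genes with at least 20 counts in all, 133 were near zero in knockout, with 29 counts over the group against 11413 in wild type, or 0.288% of the wild-type level; 119 of them had no count in any knockout library. The remaining 58 genes together held 15781 counts in knockout and 17076 in wild type, or 105% of the wild-type level after scaling. In annotation order the near-zero genes lay side by side. A first stretch of 34 genes that were not near zero, from Gm29277 to Gm28436, held the short-arm genes. Near-zero stretches of 9 and 6 genes, parted by 1 gene, came next, with 810 and 624 counts in wild type and 1 and 0 in knockout. A stretch of 19 genes that were not near zero, from Gm21292 to Gm28955, then rose in sum from 1361 to 1963 counts. Stretches of 46, 24 and 48 near-zero genes followed it. The order held 11 runs of near-zero and other genes, against a median of 82 and a lowest of 53 in shuffled orders (permutation p = 1e-05, the smallest that 100000 shuffles can give). Shuffling mixed short-arm with long-arm genes, so the low number of runs does not by itself point to a cause. Many of these gene models are near-identical copies, and their counts are uncertain one by one because shared reads could have been split or dropped. Gm21489 and Gm20873, among the Y genes with the smallest p, had 1 count each in knockout, or 0.43% (95% counting interval 0.0108% to 2.42%) and 0.617% (0.0155% to 3.48%) of wild type.

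**Figure D1:**
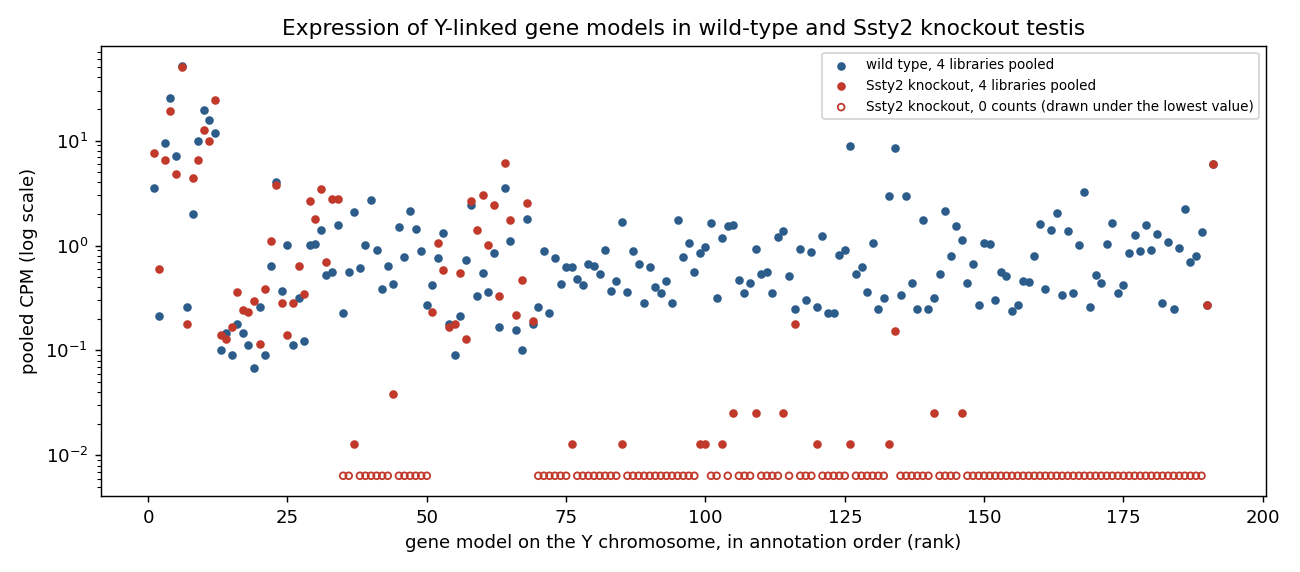
Pooled CPM (log axis) of 191 Y-linked gene models in annotation order, in wild type (blue) and Ssty2 knockout (red), 4 libraries pooled in each; open circles mark knockout counts of 0 and are drawn under the lowest value. Of the 191 models, 133 were under 5% of the wild-type level, and they lie in a few long stretches.

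Of the 8 tested short-arm genes of the single-copy list, 1 rose and 6 fell, the same counts as when adjusted over the list alone (camera adjusted p = 0.224). Zfy2, which encodes a zinc finger protein of spermatids, rose from 11.7 ± 0.776 to 24.3 ± 2.90 CPM, a log2 fold change of 1.05 ± 0.0971 (SE; n = 4 per group, adjusted p = 3.13e-07). The related gene Zfy1, named after its value was seen, had a log2 fold change of -0.54 (SE 0.158, adjusted p = 0.00861). How reads that map to both genes were counted is not given. Ddx3y fell by 0.64 on the log2 scale (SE 0.111, adjusted p = 0.000164), Usp9y by 0.65 (SE 0.115, adjusted p = 0.000201) and Kdm5d by 0.58 (SE 0.126, adjusted p = 0.0011). Eif2s3y, with a log2 fold change of -0.01, did not pass (adjusted p = 0.883). The share of all counts from the Y was 0.0351% ± 0.00355 in wild type and 0.0194% ± 0.000847 in knockout (exact permutation p = 0.0286). Over the 97 tested Y genes, 17 rose and 74 fell (camera adjusted p = 8.77e-24, and adjusted p = 0.0565 with an estimated correlation).

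**Figure D2:**
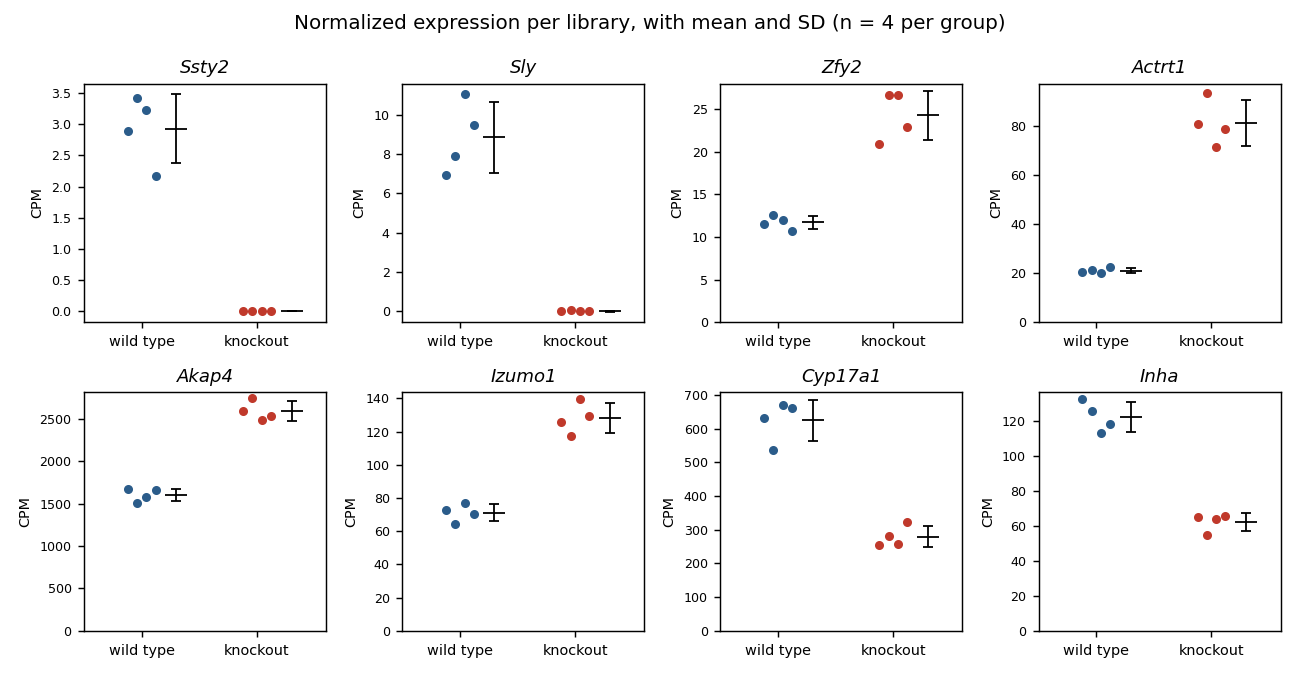
CPM of 8 genes in each library (points; wild type blue, knockout red), with the mean and SD of each group in black (n = 4 per group). Ssty2 and Sly were at or near 0 in all knockout libraries, Zfy2, Actrt1, Akap4 and Izumo1 were higher in each knockout library than in any wild-type library, and Cyp17a1 and Inha were lower in each.

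Over the whole transcriptome, 5744 of 21952 tested genes rose and 6008 fell in knockout, and 1030 rose and 688 fell by at least 2-fold. With library totals in place of TMM factors the split was 3848 higher and 8255 lower, or 31.8% of calls higher against 48.9%, around the shifted median given with the methods. Of the tested genes, 46.7% did not overlap between the groups, where chance gives 2.86% with 4 against 4. Among genes named by the rule for the largest changes, the rises were led by Afm, which encodes the plasma vitamin E-binding protein afamin (1.08 ± 0.428 to 6.06 ± 4.54 CPM, log2 fold change 2.45 ± 0.453 SE, adjusted p = 0.000276), with knockout values spread from 2.46 to 11.9 CPM. Sytl5, an X-linked synaptotagmin-like gene, rose from 2.31 ± 0.361 to 10.6 ± 0.642 CPM. Actrt1, which encodes an actin-related protein of the sperm head, rose from 21.0 ± 1.10 to 81.3 ± 9.22 CPM (log2 fold change 1.95 ± 0.0821 SE, adjusted p = 4.99e-11). Members of the X-linked Btbd35f family filled 6 of the 12 places (Btbd35f27, Btbd35f2, Btbd35f13, Btbd35f14, Btbd35f29 and Btbd35f17; log2 fold changes from 1.97 to 2.43), and H2al1a, a histone H2A variant gene of spermatids, Dhrs2 and Olfr1389 made up the rest (2.09, 2.00 and 1.95).

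Among the largest falls, Zfp990, a zinc finger gene, dropped from 32.4 ± 2.10 to 0.722 ± 0.276 CPM (log2 fold change -5.49 ± 0.152 SE, adjusted p = 2.24e-13). Mog, known as a myelin gene, had 3 counts in knockout against 347 in wild type, or 0.981% of the wild-type level (95% counting interval 0.201% to 2.89%). Gprc5a (log2 fold change -4.96), Ttc22 (-4.74), Lao1 (-4.69), Amd2 (-3.37), Yjefn3 (-3.27), Spp1 (-2.60), Vmn1r181 (-2.48), Cbs (-2.20) and Ptprn2 (-2.15) followed. Cbs encodes cystathionine beta-synthase, and Spp1 encodes osteopontin. All of these autosomal genes were lower in each knockout library than in any wild-type library, which the naming rule required of them. Zfp990, Mog, Gprc5a, Ttc22, Lao1, Amd2 and Yjefn3 are among 52 autosomal genes at least 8-fold lower. For these 52, a difference in genetic background between the groups is a candidate explanation, given with the other observations.

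Genes of spermatids rose together. All 26 tested round spermatid markers rose, also when adjusted over the list alone, with a median log2 fold change of 0.48 (camera adjusted p = 9.78e-14, and adjusted p = 0.0814 with an estimated correlation). Izumo1, which encodes the sperm protein that binds the egg, rose from 71.2 ± 5.36 to 128 ± 9.22 CPM (log2 fold change 0.85 ± 0.0677 SE, adjusted p = 7.50e-08). Gsg1 rose from 848 ± 42.0 to 1297 ± 27.3 CPM, the sperm calcium channel gene Catsper4 from 89.5 ± 8.41 to 155 ± 3.45 CPM and Tex21 from 140 ± 14.4 to 252 ± 23.5 CPM. Of 26 elongating spermatid and chromatin compaction genes, 22 rose and none fell, in both adjustments (median 0.49, camera adjusted p = 1.5e-10, and adjusted p = 0.113 with an estimated correlation), among them Oaz3 (0.59), Spem1 (0.66) and Smcp (0.56). The protamine genes Prm1 and Prm2, whose products replace histones in sperm, rose by 0.65 and 0.70 on the log2 scale, to 4406 ± 469 and 5231 ± 362 CPM.

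Of 34 flagellum and motility genes, 28 rose and 1 fell, or 29 and 1 adjusted over the list alone (median 0.38, camera adjusted p = 7.2e-10, and adjusted p = 0.0942 with an estimated correlation). Akap4, the main scaffold protein gene of the fibrous sheath, rose from 1603 ± 74.2 to 2596 ± 113 CPM (adjusted p = 2.99e-08), the glycolysis gene Pgk2 rose by 0.58 and Gapdhs by 0.49. The member that fell was Dnah8 (-0.55), named after its value was seen. Of 22 sperm-egg interaction and acrosome genes, 19 rose and 1 fell, or 20 and 1 adjusted over the list alone (median 0.44, camera adjusted p = 9.62e-07, and adjusted p = 0.0814 with an estimated correlation). Acrbp (0.48), Dcst2 (0.59) and Spaca6 (0.53) rose, and the one that fell was Tex101 (-0.50), which is also among the spermatocyte markers. Of 29 genes of the autosomal multicopy spermatid list, 23 rose and none fell in both adjustments (median 0.51, camera adjusted p = 1.29e-07, and adjusted p = 0.07 with an estimated correlation). They included Tssk3 (0.67) and, although it lies on the X, Tcp11x2 (1.27). In the same libraries the Sertoli and Leydig cell lists and the share of mitochondrial counts were lower.

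Markers of Leydig, Sertoli and peritubular myoid cells fell. Of 19 markers of Leydig cells, which make testosterone, 17 fell and none rose, or 18 and none adjusted over the list alone, with a median log2 fold change of -0.98 (camera adjusted p = 2.38e-13, and adjusted p = 0.0234 with an estimated correlation). Cyp17a1, which encodes a steroid hydroxylase and lyase of androgen synthesis, fell from 624 ± 61.4 to 280 ± 30.6 CPM (log2 fold change -1.16 ± 0.0788 SE, adjusted p = 1.16e-08). Cyp11a1, which encodes the enzyme that cleaves the cholesterol side chain, fell from 254 ± 32.1 to 127 ± 10.2 CPM, and the luteinizing hormone receptor gene Lhcgr from 28.9 ± 3.49 to 9.75 ± 2.11 CPM. Aldh1a1 fell by 1.08 on the log2 scale. Of 26 Sertoli cell markers, 22 fell and none rose, or 23 and none adjusted over the list alone (median -0.61, camera adjusted p = 5.12e-12, and adjusted p = 0.0942 with an estimated correlation). The inhibin subunit genes Inha and Inhbb fell by 0.97 and 0.83 on the log2 scale, Aard by 0.77 and Vim by 0.62.

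Of 12 peritubular myoid cell markers, 9 fell and 1 rose in both adjustments (median -0.57, camera adjusted p = 0.00772, and adjusted p = 0.351 with an estimated correlation). Myl9 (-0.67), Myh11 (-0.59) and Cald1 (-0.69) fell, and the smooth muscle actin gene Actg2 rose by 0.47 at 257 ± 10.7 CPM. Of 16 macrophage and immune genes, 9 fell and 1 rose, or 10 and 1 adjusted over the list alone (median -0.59, camera adjusted p = 0.0644). Mrc1 (-0.56), Csf1r (-0.68) and Lyz2 (-0.64) fell and Aif1 rose by 0.52, from 258 ± 19.6 to 369 ± 27.0 CPM. Without knockout replicate 1 the same list had an adjusted p of 0.0084, without wild-type replicate 2 of 0.0421 and without wild-type replicate 3 of 0.0484. Of 12 endothelial genes, 3 fell (Cdh5 by 0.46, Eng by 0.49 and Egfl7 by 0.56) and none rose in both adjustments (camera adjusted p = 0.305). None of 4 erythroid genes passed (camera adjusted p = 0.934, the same count adjusted over the list alone). Of 7 tested epididymis genes, 1 rose and 2 fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.721). Cst8, which the testis also expresses, rose by 0.46 at 227 ± 13.6 CPM. Spink8 fell by 1.54 on the log2 scale and Cuzd1 by 0.34 (adjusted p = 0.0449). The Cuzd1 call ended in 10 of 17 alternatives, among them those without knockout replicate 1, 2 or 4 or wild-type replicate 2, 3 or 4, and its adjusted p ran from 0.0074 to 0.115 over all of them.

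Spermatogonial genes also fell. Of 19 spermatogonial markers, 14 fell and 2 rose, or 15 and 2 adjusted over the list alone (median -0.72, camera adjusted p = 0.000109, and adjusted p = 0.0942 with an estimated correlation). Uchl1, Dmrt1 and Kit, the last a receptor gene of differentiating spermatogonia, fell by 0.78, 0.78 and 0.79 on the log2 scale and Etv5 by 0.66. The members that rose, named after their values were seen, were Gfra1 (0.47) and Pou5f1 (0.72). Meiotic spermatocyte markers went both ways, with 6 of 26 higher and 11 lower in both adjustments (camera adjusted p = 0.34). Dmc1, a meiotic recombinase gene, fell by 0.70 and Rad51ap2 by 0.91, while Spag6 rose by 0.49. Of 24 piRNA pathway genes, 4 rose and 8 fell in both adjustments (camera adjusted p = 0.672), with Tdrd6 (0.33), Gtsf1 (0.29), Mael (0.24) and Tdrd7 (0.23) higher and Fkbp6 (-0.52) and Mov10l1 (-0.34) among those lower. Among 23 regulators of sex chromosome silencing and spermatid chromatin, 8 rose and 9 fell in both adjustments (camera adjusted p = 0.672). Spin1, an autosomal gene related in sequence to Ssty, fell from 43.6 ± 2.27 to 28.3 ± 0.747 CPM (adjusted p = 1.25e-06). Scml2 fell by 0.72 on the log2 scale, and Rfx2 and Sox30, which encode transcription factors of spermiogenesis, rose by 0.42 and 0.34.

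**Figure D3:**
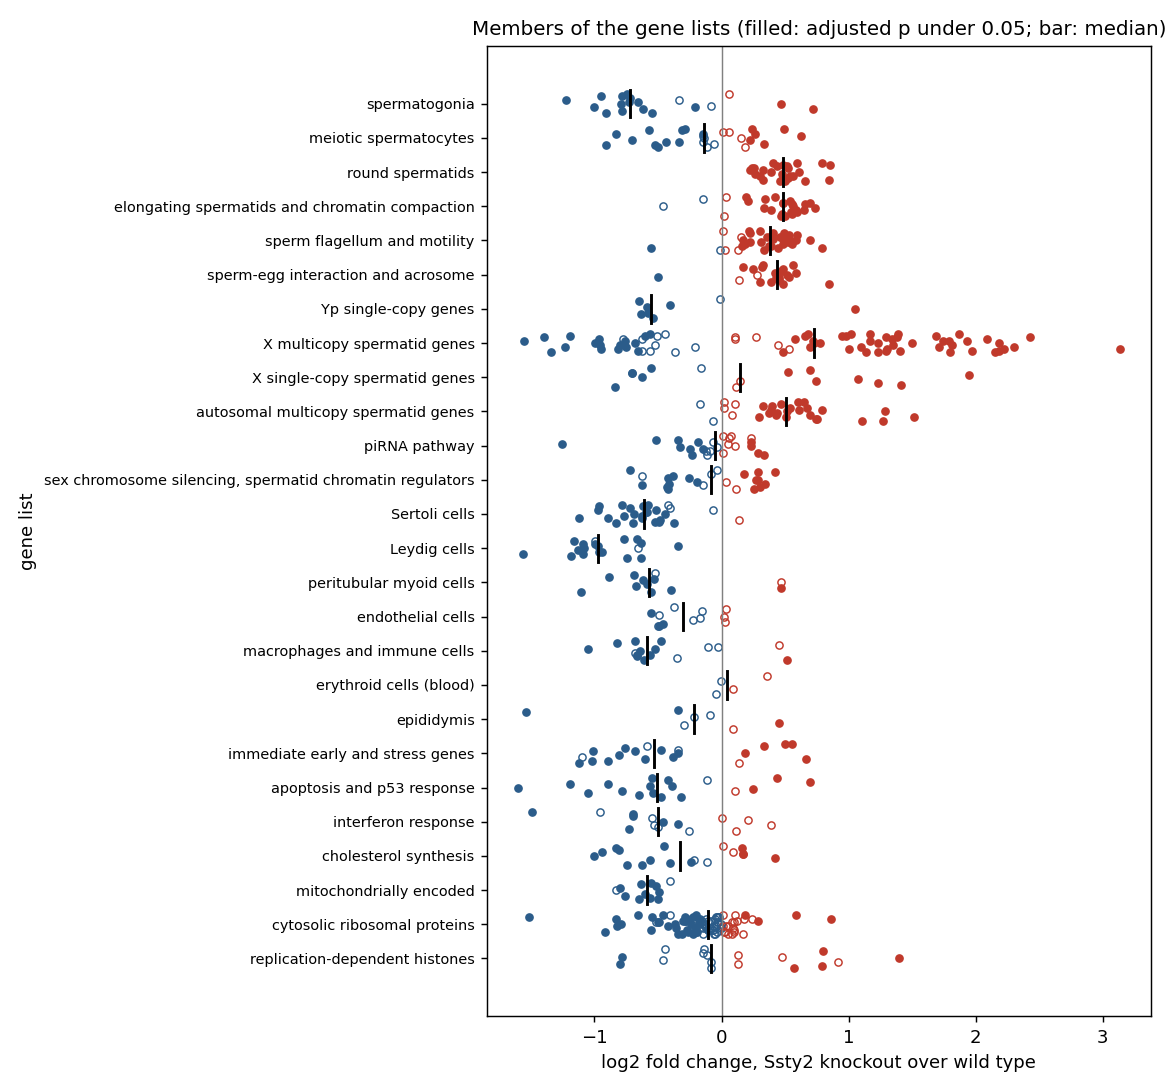
Log2 fold change (knockout over wild type) of each tested member of 26 gene lists; filled points have an adjusted p under 0.05, red is higher and blue lower in knockout, and the black bar is the list median. The Y long-arm list and a list with 1 tested member are not drawn; the round spermatid list has a median of 0.48 and the Leydig cell list one of -0.98.

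Mitochondrially encoded genes fell, 10 of 12 over all genes and 12 of 12 adjusted over the list alone (median -0.58, camera adjusted p = 1.65e-05, and adjusted p = 0.0942 with an estimated correlation). Among them were mt-Cytb (-0.65) and mt-Co1 (-0.60). The share of counts from the mitochondrial genome was 1.20% ± 0.133 in wild type and 0.727% ± 0.0447 in knockout (exact permutation p = 0.0286). Of 18 cholesterol synthesis genes, 10 fell and 3 rose in both adjustments (median -0.32, camera adjusted p = 0.0172, and adjusted p = 0.468 with an estimated correlation). Dhcr7 fell from 32.6 ± 4.10 to 16.3 ± 1.48 CPM. Hmgcs1, Insig1 and Nsdhl fell by 0.56, 0.83 and 0.74 on the log2 scale, while Fdft1 (0.42), Cyp51 (0.17) and Sqle (0.16) rose. Of 18 apoptosis and p53 response genes, 13 fell and 3 rose in both adjustments (median -0.51, camera adjusted p = 0.0226, and adjusted p = 0.351 with an estimated correlation), among them Gadd45a (-1.61), Ccng1 (-0.79), Trp53 (-0.55) and Pmaip1 (-1.05); Bbc3 (0.70), Bcl2l11 (0.43) and Mdm2 (0.25) rose. Of 89 cytosolic ribosomal protein genes, 32 fell and 4 rose in both adjustments (median -0.11, camera adjusted p = 0.00504, and adjusted p = 0.65 with an estimated correlation). Rps3 and the X-linked Rpl10 and Rps4x fell by 0.65, 0.83 and 0.82 on the log2 scale, and Rpl29 (0.86), Rplp0 (0.29) and Rpsa (0.18) were among those that rose. The processed pseudogene Rpsa-ps10, chosen after its value was seen, had a log2 fold change of -4.33. How reads shared between a gene and its pseudogenes were counted is not given, so small rises such as that of Rpsa are uncertain.

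Immediate early and stress genes went both ways, 5 of 20 higher and 11 lower, or 5 and 12 adjusted over the list alone (camera adjusted p = 0.208). Hmox1 (-0.81) and Btg2 (-1.12) fell and Klf4 (0.50), Nr4a1 (0.56), Hspa1a (0.67), Ddit3 (0.33) and Dnajb1 (0.18) rose. Of 15 interferon response genes, 6 fell and none rose, or 5 and none adjusted over the list alone (camera adjusted p = 0.157), among them Bst2 (-0.72) and Irf9 (-0.70). Of 17 replication-dependent histone genes, 4 rose and 2 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.398); the median was -0.08 while the mean was 0.13 and the test pointed up. Hist1h3a rose from 5.79 ± 0.799 to 15.2 ± 2.24 CPM. Hist1h4a (0.80), Hist1h1a (0.79) and Hist1h2bp (0.57) rose, and Hist1h1c and Hist1h2bc fell by 0.80 and 0.78 on the log2 scale. The list of innate sensing receptors on the X had 1 tested member, Tlr7, which did not pass (log2 fold change -0.75 ± 0.373 SE, adjusted p = 0.1). Without knockout replicate 2 Tlr7 passed (adjusted p = 0.0364), and its adjusted p ran up to 0.27 over all alternatives.

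On the X chromosome, many genes rose at least 2-fold while more genes fell than rose. Of 836 tested X genes, 304 rose and 344 fell, and 205 (24.5%) rose and 35 fell by at least 2-fold; the odds of a rise of at least 2-fold were 7.99 times those of other genes (Fisher's exact test, adjusted p = 9.18e-91). The median log2 fold change was -0.24, while the mean was 0.10 and camera pointed up (adjusted p = 0.0436, and adjusted p = 0.67 with an estimated correlation). That call also ended without knockout replicate 4 (adjusted p = 0.0608), wild-type replicate 1 (0.185) or wild-type replicate 3 (0.0732). The share of all counts from the X rose from 1.44% ± 0.0534 to 1.75% ± 0.0319 (exact permutation p = 0.0286). The genes with the smallest p all rose: Fam122c from 32.8 ± 0.879 to 106 ± 0.803 CPM (log2 fold change 1.69 ± 0.0558 SE, adjusted p = 2.61e-12), Ppp1r2-ps9 by 1.68, Ctag2 by 1.78, 1700003E24Rik by 1.66 and Gm15104 by 1.92 on the log2 scale.

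Of 75 genes of the X-linked multicopy spermatid list, 44 rose and 17 fell, or 44 and 19 adjusted over the list alone (median 0.73, camera adjusted p = 9.05e-08, and adjusted p = 0.0814 with an estimated correlation). Cypt3 (1.23), Cypt2 (1.29), Mageb5 (1.82) and H2al1m (1.38) rose. Slxl1 and Srsx, named after their values were seen, rose by 1.35 (adjusted p = 0.000114) and 1.17 (adjusted p = 0.00197). Slxl1 is an X-linked relative of Sly. Of 9 tested Xlr genes 6 fell and none rose, and of 7 tested Magea genes 5 fell and none rose; these families were also named after their values were seen, and Xlr3b (-1.55) and Magea8 (-1.34) were among those that fell. Copies within these families are near-identical, so the values of single members are uncertain. Of 15 genes of the X-linked single-copy spermatid list, 7 rose and 5 fell in both adjustments (median 0.14, camera adjusted p = 0.000152, and adjusted p = 0.0942 with an estimated correlation). Fam47c (1.41), Akap4 and Actrt1 rose, as did Cypt3, which is also in the multicopy list, and Chic1 (-0.84), Pgrmc1 (-0.71), Tex16 (-0.70), Tktl1 (-0.62) and Dcaf12l1 (-0.55) fell. Rbmxl2, a member that lies on chromosome 7, did not pass (log2 fold change -0.16, adjusted p = 0.0794). Outside the multicopy list, 260 of 761 X genes rose and 327 fell, and 171 rose and 30 fell by at least 2-fold.

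**Figure D4:**
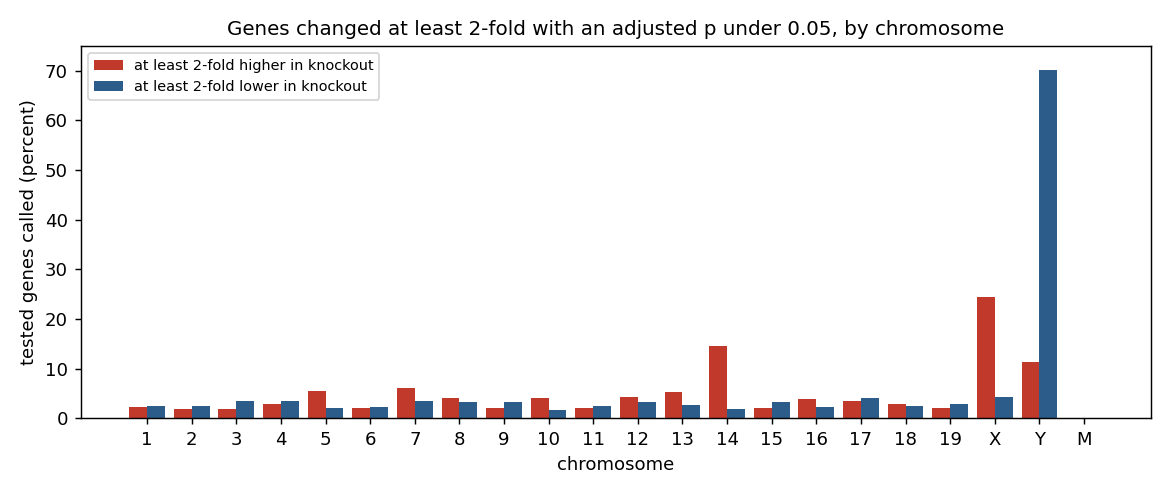
Percentage of tested genes on each chromosome that were called at an adjusted p under 0.05 and changed at least 2-fold (red higher, blue lower in knockout). The X has 24.5% and chromosome 14 has 14.5% of genes higher, and the Y has 70.1% lower.

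Among the autosomes, chromosome 14 had 371 genes that rose and 203 that fell of 922 tested, and 134 (14.5%) rose by at least 2-fold (odds ratio 3.82, Fisher's exact test, adjusted p = 2.07e-31; camera adjusted p = 0.0264, and adjusted p = 0.0565 with an estimated correlation). On chromosome 7, 99 of 1646 genes rose by at least 2-fold (odds ratio 1.33, Fisher's exact test, adjusted p = 0.0182). Such rises were rarer than elsewhere on chromosomes 1, 2, 3, 4, 6, 9, 11, 15 and 19. Their odds ratios ran from 0.365 to 0.591 (Fisher's exact test, adjusted p from 8.74e-09 to 0.00288). Among all autosomal genes, 782 rose and 574 fell by at least 2-fold. Of 20 tested mitochondrial genes, 14 fell (camera adjusted p = 0.00034, and adjusted p = 0.236 with an estimated correlation).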

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

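The tests of the Y, both comparisons of X-linked with autosomal spermatid lists and the comparison of Leydig with Sertoli genes were chosen after the results were seen, as were the splits of the libraries for the counts of genes, lists at the preset correlation and chromosomes; the test of little-sharing X genes, the test of length and GC content and the splits with an estimated correlation were written down before their results were seen.

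The near-zero counts along the Y reached beyond the gene model named Ssty2, though other copies of Ssty2 may be among the near-zero genes. Of the 133 near-zero genes, 52 (39.1%, 95% binomial interval 30.8% to 47.9%) share no 31-base word with Ssty2, and genes that share words were not shown to be near zero more often (73.6% against 64.2%, Fisher's exact p = 0.203), so a loss of reads shared with Ssty2 is argued against for those 52. For the other 81, a lost gene copy and a lost share of reads cannot be told apart, because the counts do not keep where a shared read came from; of the genes not near zero, the 29 that share words with Ssty2 stood at 178% of wild type (95% counting interval 168% to 189%) and the 29 that share none at 96.5%. A lower share of spermatids is also argued against, since the mean log2 CPM of the round spermatid list was 0.485 higher in knockout (exact permutation p = 0.0286). The 11 runs along the annotation order would follow from a loss of parts of the long arm beyond Ssty2, which is a hypothesis. They do not single it out, since shuffling mixed short-arm with long-arm genes and neighbouring copies may share reads. A single lost stretch would also have to spare the 19 genes from Gm21292 to Gm28955. In this annotation order they lie between near-zero stretches and were not near zero. A Y chromosome of another strain in the knockout stays open as untested.

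Some X-linked spermatid genes rose further than autosomal ones. A larger share of spermatids was first tested by the mean log2 CPM of the X multicopy list less that of 25 autosomal round spermatid genes, which was 0.0756 higher in knockout (exact permutation p = 0.371) and decided nothing, since members went both ways; for the X-linked members of the single-copy list the difference was -0.166 (exact permutation p = 0.0571). A second test, chosen after the first had come out so, found that 37 of 88 X-linked members of both X lists rose by at least 2-fold, against 3 of 118 autosomal members of the spermatid lists, of which 100 rose (Fisher's exact p = 3.15e-13; 0 of 96 without the autosomal multicopy list, as the test was first run), and 34 of 75 against 3 of 28 within the multicopy lists (Fisher's exact p = 0.00106) and 3 of 13 against 0 of 90 outside them (Fisher's exact p = 0.00162), which argues against a larger share that raises all spermatid genes alike as the whole cause. Reads shared between near-identical copies are argued against as the whole cause, since 18.2% of 373 X genes with little sharing rose by at least 2-fold, against 3.38% of 9297 such autosomal genes (odds ratio 6.38, Fisher's exact p = 1.46e-27), while 47.7% of these X genes fell. An effect of the genotype on X-linked genes in spermatids is a candidate explanation and no more than a hypothesis. It cannot be laid to Ssty2 alone, since 133 of 191 Y-linked genes, Sly among them, were near zero in the same libraries. A change in the stages of spermatids present stays open, untested. So does a difference in genetic background between the groups, which the labels do not describe.

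The Leydig, Sertoli and peritubular myoid lists fell at the preset correlation, of which the Leydig call held with an estimated one, while spermatid lists rose. Camera did not call the endothelial, macrophage and erythroid lists; fry called the first 2 of these (adjusted p = 0.0202 and 0.0367). If somatic cells were all diluted alike, genes expressed in them alone would fall alike. The Leydig list fell further than the Sertoli list (difference -0.365 on the log2 scale between group means of the per-library difference, exact permutation p = 0.0286). That argues against 1 common dilution as the whole cause only if both lists are equally specific to their cells. This was not tested, and the Sertoli marker Dmrt1 is also among the spermatogonial markers. Bias from gene length or GC content is argued against, since after subtracting the median change of genes of like length and GC the Sertoli median was -0.55, the Leydig median -0.96 and the round spermatid median 0.42, with every member on its list's side (exact binomial p = 2.98e-08, 3.81e-06 and 2.98e-08). What stays open, untested, is a change in the make-up of the tissue, with or without a change of expression within Leydig cells, both of which may follow the genotype. A difference in genetic background between the groups, which the labels do not describe, cannot be told apart from the genotype here.

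The real split gave 5744 higher and 6008 lower genes. Of the 35 splits of the 8 libraries, 1, the real one, gave as many, with a highest of 0 in the others. In the others the genotypes are mixed, so any difference between them widens the spread within groups and can keep genes from passing. The splits therefore do not exclude chance, and they cannot tell genotype from another difference between the groups. At the preset correlation the real split called 16 gene lists, 8 of 35 splits called as many and the highest other called 18. Some of the other splits divide the genotypes unevenly and so keep part of their difference. They do not measure chance alone, so chance is neither excluded nor shown as the source of these calls. With an estimated correlation the real split called 2 lists and the highest other 1, and 1 of 35 splits gave as many. For chromosomes the real split called 4 and the highest other 3, again 1 of 35.

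Single libraries stood apart from the other 3 of their group, by Dixon's test, in 34 of 332 groups of values, or 10.2%. Chance gives about 1 in 20 groups, and values of one library are not independent. Wild-type replicates 2 and 4 and knockout replicate 2 each gave 7. In wild-type replicate 4 the 10 largest genes took 3.652% of counts (others at most 3.15%), genes without a symbol took 1.065% (others at most 0.46%), and the mean log2 CPM was 3.482 for macrophage and immune genes (others at most 3.123) and 1.537 for replication-dependent histones (others at most 1.315). In the same library Dmrt1 was at 35.15 CPM, Lyz2 at 30.87 CPM and 1700003E24Rik at 42.94 CPM, each above the rest. Wild-type replicate 2 had the regulators of sex chromosome silencing at 6.422 (others at most 6.354), Kit at 45.32 CPM, above the rest, and, below the rest, Gsg1 at 785.6, Catsper4 at 77.07, Gapdhs at 902.1, Sox30 at 167.7 and Stat2 at 7.786 CPM. Wild-type replicate 1 had autosomal multicopy spermatid genes at 4.882 (others at most 4.818), mitochondrially encoded genes at 6.498 (others at least 6.72), Ttc22 at 10.5 CPM and Ctag2 at 44.98 CPM, both above the rest. Wild-type replicate 3 had endothelial genes at 2.031 (others at most 1.825), Fkbp6 at 41.59 CPM, below the rest, and Insig1 at 33.06 CPM, above them.

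Among the knockout libraries, replicate 1 had a mitochondrial share of 0.6609% (others at least 0.7406%) and Csf1r at 13.31 CPM (others at most 9.513). Replicate 2 had mitochondrially encoded genes at a mean log2 CPM of 6.108 (others at most 6.067), Spag6 at 131 and Inha at 54.84 CPM, below the rest, Tcp11x2 at 103.1, Rnase10 at 6.15 and Gm15104 at 172.5 CPM, above them, and the only Sly count of the group, worth 0.047 CPM. Insig1 was at 17.23 CPM in replicate 3, above the rest. In replicate 4, Nsdhl was at 8.383 CPM, below the rest, and Gm21489 and Gm20873 each had the only count of the group, worth 0.058 CPM.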

How the results depend on the processing

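TMM from autosomal genes, and list and chromosome tests without a count filter, with a stricter one and with library totals, were tests chosen after the data were seen; the other alternatives were fixed before. No result with a call changed direction; the median of the erythroid list, which was not called, turned to -0.10 with library totals. The count of higher genes ran from 3848 to 5915 and that of lower genes from 5367 to 8255 over tools, scalings, filters, the block and left-out libraries. Leaving out 1 library gave 5017 to 5549 and 5367 to 5975, a change of at least 2-fold left 1030 and 688, and an adjusted p under 0.01 left 4312 genes higher in knockout and 4481 genes lower in knockout. Of 133 named genes besides Ssty2, 129 stayed on their side of the threshold in every alternative in which they were tested. The others were Cuzd1, Tek (called without knockout replicate 1 or wild-type replicate 4, among others), and Rnase10 and Tlr7 (both called without knockout replicate 2). The Ssty2 call held in all 16 of its alternatives; leaving out multicopy genes leaves no value for it. With the replicate number as a block 5915 genes were higher and 6203 lower, and the block changed no call of a list or chromosome. Deviations of same-numbered libraries from their group means correlated at 0.002 to 0.08, against -0.066 to 0.041 for other pairs across groups. Of the 8 libraries, 5 correlated best with their own number, more than chance gives on average, so a pairing is not excluded. The correlations were weak and the labels name no pairing, so the number was not used in the main test.

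An estimated correlation, which widens the error of a list whose genes vary together, left 2 of 16 lists called. The adjusted p became 0.0942 for spermatogonia, flagellum and motility, X-linked single-copy spermatid genes, Sertoli cells and mitochondrially encoded genes. It was 0.0814 for round spermatids, sperm-egg interaction and acrosome and X-linked multicopy spermatid genes, 0.113 for elongating spermatids, 0.07 for autosomal multicopy spermatid genes, 0.351 for peritubular myoid cells and for apoptosis and p53 response, 0.468 for cholesterol synthesis and 0.65 for cytosolic ribosomal proteins. At the preset correlation these 14 lists ran from 1.35e-23 to 0.0398 over the alternatives. It called 0 chromosomes, with 0.0565 for chromosome 14 and the Y, 0.67 for the X and 0.236 for the mitochondrial genome.

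Fry, which tests a list on its own and not against other genes, called 6 further lists: short-arm Y genes (0.0479), endothelial cells (0.0202), macrophages and immune cells (0.0367), immediate early and stress genes (0.0131), interferon response (0.0131) and replication-dependent histones (0.0332). Camera gave these 6 from 0.00619 to 0.942 over the alternatives at the preset correlation. Fry did not call cytosolic ribosomal proteins (0.0511). It called 12 chromosomes, among them chromosome 2 (0.000785), 3 (0.0397), 4 (0.0087), 5 (0.002), 9 (0.0143), 11 (0.00432), 16 (0.0105) and 19 (0.000869), which camera gave from 0.656 to 0.955 at the preset correlation.

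Without a count filter 2 chromosomes were called, as chromosome 14 (0.0762) and the X (0.255) were not, and macrophages and immune cells were (0.00619); the cause was not tested. Leaving out 1 library gave macrophages and immune cells 0.0084 (without knockout replicate 1) to 0.154, called also without wild-type replicate 2 or 3. It gave the X 0.0213 to 0.185 (without wild-type replicate 1), not called also without knockout replicate 4 or wild-type replicate 3. The X ran from 0.00662 to 0.67 over all alternatives. A gene of 0 counts in knockout is bounded at 0.0383 CPM over the group, which limits the folds of low Y-linked genes.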

Other observations

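The tests of neighbouring genes and of genes at least 8-fold lower were chosen after the results were seen, as were the gene types; the test of lincRNA genes at like expression was written down before its result was seen.

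LincRNA and antisense genes rose as groups, while more protein-coding genes fell than rose. Of 1966 tested lincRNA genes, 808 rose and 121 fell, with a median log2 fold change of 0.37 (camera adjusted p = 6.02e-06, and adjusted p = 0.0123 with an estimated correlation). Of 1124 genes annotated as antisense, whose reads cannot be told from those of their partner genes, 414 rose and 49 fell (median 0.29, camera adjusted p = 0.000196, and adjusted p = 0.0184 with an estimated correlation). Of 126 bidirectional promoter lncRNA genes, 23 rose and 10 fell, which did not pass (median 0.11, camera adjusted p = 0.365, and adjusted p = 0.624 with an estimated correlation). Protein-coding genes went the other way, with 3719 of 16016 higher and 5555 lower (median -0.10, camera adjusted p = 1.65e-05, and adjusted p = 0.000752 with an estimated correlation). Camera compares a class with all other genes, and protein-coding genes are most of those tested. Its p-value therefore restates in part the rise of the other classes. Fry, which tests a class on its own, also pointed down (adjusted p = 8.02e-05), a result that rests on the scaling. Low expression does not account for the lincRNA rise, since in 10 of 10 groups of genes of like expression the lincRNA median lay above the protein-coding median, by 0.001 to 0.718. The median difference was 0.596 on the log2 scale (permutation p = 0.0001, the smallest that 10000 draws can give). That many of these lincRNA and antisense genes may be transcribed in spermatids, whose markers rose as well, is a hypothesis that was not tested.

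Neighbouring autosomal genes rose together. Adjacent tested genes that both rose by at least 2-fold made 173 pairs, against a median of 44 and a highest of 69 in orders shuffled within chromosomes (permutation p = 0.0001, the smallest that 10000 shuffles can give), with 68 pairs on chromosome 14, 34 on chromosome 7 and 16 on chromosome 5. Named after their values were seen, Gm4181 on chromosome 14 rose from 4.94 ± 0.495 to 27.7 ± 1.84 CPM (n = 4 per group, adjusted p = 4.25e-11), Gm17067 on chromosome 7 from 5.01 ± 0.369 to 20.7 ± 2.71 CPM and Gm17019 on chromosome 5 from 2.86 ± 1.73 to 14.3 ± 4.96 CPM. Among the 134 genes of chromosome 14 that rose by at least 2-fold, the median share of words found in another gene was 75.1%, so reads shared between copies could make several genes of a cluster rise together. Of the 173 pairs, 26 had little sharing in both genes. In a separate count among the 9297 autosomal genes with little sharing, genes become neighbours once those between them are left out. There were 35 pairs against a median of 12 and a highest of 27 in shuffled orders (permutation p = 0.0001). This points to clusters of neighbouring genes that rose together and were not made by shared reads alone. Whether they follow the genotype, the genetic background or reads of overlapping genes was not tested.

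Autosomal genes with changes of at least 8-fold went mostly down. There were 52 lower and 7 higher genes (exact binomial p = 1.36e-09, genes taken as independent), and the lower genes lay on all 19 autosomes. The 3 of them with 0 counts in knockout were at least 15.9-fold lower against 3 counts over the group. Processed pseudogenes made up 20 of the 52, or 38.5%, against 3.46% of other tested autosomal genes (odds ratio 17.4, Fisher's exact p = 3.36e-16). Protein-coding genes made up 17, among them Zfp990, Mog, Gprc5a, Ttc22, Lao1, Amd2 and Yjefn3. Of all 796 tested processed pseudogenes 229 rose and 90 fell, and the class did not pass (median 0.22, camera adjusted p = 0.105, and adjusted p = 0.0646 with an estimated correlation). Of 117 transcribed processed pseudogenes 46 rose and 11 fell (camera adjusted p = 0.000707, and adjusted p = 0.0123 with an estimated correlation). Chosen after their values were seen, Gm8730, a processed pseudogene, fell from 88.1 ± 11.8 to 3.14 ± 0.449 CPM (adjusted p = 8.56e-14) and Rpsa-ps10 from 30.1 ± 0.856 to 1.48 ± 0.16 CPM. How reads shared between a processed pseudogene and its parent gene were counted is not given, so the levels of these pseudogenes are uncertain. A candidate explanation is a difference in genetic background between the groups, which the labels do not describe, because retrocopies and their sequence differ between mouse strains; an effect of the genotype on these genes stays open, untested.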
